A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

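RNA of 4 cultures of a ura3 and phr2 deletion strain of Halobacterium salinarum NRC-1 was hybridised on 8 two-colour arrays, 2 per culture with exchanged dyes (Alexa 532 and Alexa 647), against a common reference RNA taken at an optical density of 0.5 to 0.6, per the labels. Groups (high or low oxygen, light or dark) and the dye of each channel were taken from the labels, which name 1 culture per condition. As no condition has a second culture, the p-values do not measure a spread between replicate cultures. They rest on the departure of the 4 cultures from additive effects and on a spread pooled over all positions. Both include any technical part.

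For each array the deposited scan table gives the mean spot intensity and the local background intensity with its standard deviation for each dye at a high and a low gain, per the file headers. The deposited tables also give a spot confidence in percent, which was below 100 where a pixel of the spot had reached the ceiling of 65535. The series table deposited by the authors gives 1 log10 ratio per spot. Scanner, image software and the authors' normalization are not given in the sources used here. Compared with the scans, the authors' log10 values equal the log10 ratio of the 532 over the 647 mean intensity at high gain, plus a constant per array, within 0.002 for 74.2% to 99.8% of unsaturated spots, without background subtraction and without turning the dye. Their medians were 0.0366 to 0.102. This match held for spots sorted by set row, row, set column and column (r of 0.637 to 0.703 over all spots) and not by spot number (0.0656 to 0.189), and gene symbols were assigned in the former order. Zeros (up to 627 per array) and missing values (469 on 1 array) of that table were treated as missing. The source of the constant and the treatment of the remaining spots are not given in the sources used here.

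A position has 4 spots, 2 adjacent and 2 copied 5376 spots later. The platform annotation gave a symbol for 532 spots, 4 for each of 133 genes, and none had several symbols; these symbols can be old. No genome of the strain was used, so no coordinates are given.

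Saturated spots at high gain took the rescaled low-gain value, fitted by a line over unsaturated spots between 8000 and 40000. The intensities were background-corrected with normexp (offset 50), normalized within each array by loess and turned to log2 culture over reference in limma 3.58.1 (R 4.3.3). The 4 spots of a position and then the 2 arrays of a culture were averaged, so that a dye effect cancels. A position counted as above background on an array where the mean of its spots exceeded the local background by 1 standard deviation of the background pixels. Median spot intensities at high gain were 2454 to 6533 for Alexa 532, over backgrounds of 1813 to 3247, and 4694 to 11966 for Alexa 647, over 2719 to 4889. Low-oxygen arrays had 1008 to 1240 positions above background in the culture channel and high-oxygen arrays 1093 to 1745. In the channel of the common reference RNA they had 884 to 1309 and 1245 to 1895. The low-oxygen arrays thus tended to be dimmer in both channels, and array brightness is not separated from oxygen. The 2 arrays of a culture correlated with r of 0.0552 to 0.26 across positions, and arrays of different cultures with the culture in the same dye with 0.426 to 0.67. Arrays of different cultures with the culture in the other dye had -0.0363 to 0.266, and their median, 0.154, was close to that of the 2 arrays of a culture, 0.157.

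An additive model of oxygen and light was fitted to the 4 culture values in limma with 1 residual degree of freedom, and the empirical Bayes prior added 7.38. The difference of the oxygen effect between light and dark thus serves as the error and has no test of its own. Of the 8.38 total degrees of freedom most come from the prior, which pools the spread over all positions. The SEs given therefore lean mostly on that pooled spread. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Of 23 gene lists fixed before the data were examined, 7 had at least 4 measured genes. These were tested with camera (preset correlation 0.01, then an estimated correlation) and fry. Camera sets a list against all other positions, most of which have no symbol, so a shift of the named genes in general also enters its result. A further 8 lists were added once the gene names, but no group values, had been seen. With 1 residual degree of freedom the estimated correlation was poorly determined, from -0.2 to 1 over the lists. Failing with it therefore does not count against a list. By fry no list passed in its directional test. Its mixed test, which ignores direction, called none for oxygen or light. Against the reference it called 2 of the 7 planned lists, motility and pyrimidine synthesis (both adjusted p = 0.0385), and 1 added list, the aminoacyl-tRNA synthetases (adjusted p = 0.0304). The pyrimidine list includes pyrF, the name here of the deleted ura3, with the lowest value of the list (-0.28). That gene was above background on no array, and the list was not tested without it. The named genes are pyrF, arcA, arcC, sop1 and sop2 as genes of the deletions and of known oxygen or light biology, up to 15 named genes each way for oxygen and light and up to 10 against the reference with the largest difference, first among calls and then, where fewer passed, among genes of equal sign in all 4 same-dye comparisons or on all 8 arrays, and for each list described the 2 to 4 members with the largest difference. In the groups for oxygen and light, where nothing passed, members are given only as far as they matter. The gene phoU in the oxygen comparison was named after its values were seen.

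The fit was tested on simulated data with the spread and dye bias of these arrays and 200 of 2688 positions changed, 20 times for each comparison. The noise was drawn independently for each spot, with no correlation between genes and no tie to intensity. In the arrays the prior SD was 0.116 over all positions and 0.080 over those above background on all arrays. The rates below, also for the gene list, therefore hold for such simulated noise only. For the oxygen effect it called 8% of changes of 0.25 on the log2 scale, 69.8% of 0.5 and 99.9% of 1, for the light effect 5.2%, 58.1% and 99.4%, and for the comparison with the reference 64.9%, 99.5% and 100%. The median share of false calls was 11.9%, 6.38% and 6.84%, above the nominal level. The prior was poorly determined with 1 residual degree of freedom, and for oxygen its estimate was infinite in 6 of 20 simulations. In the oxygen comparison camera called a shift of 0.2 in the 7 purine genes in 18 of 20 simulations. Doubling the signal above background in the culture channel of 200 positions gave a median log2 of 0.81 at the brighter positions and 0.52 at the dimmer ones, so in that test the folds came out smaller than the change in signal.

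Alternatives fixed before the data were examined were no background correction, plain subtraction, normexp with offset 0, median centring, scaling between arrays, the authors' deposited log10 table, the median of the spots, leaving out the dimmest 25% of positions, each dye orientation alone, each factor alone, all 8 arrays with a dye term and the culture as random block (statmod 1.5.0), a prior following intensity, and leaving out each array. The low-gain scan alone, the high-gain scan alone, the positions above background on all arrays and the estimated correlation under the other settings were added after seeing the data. Leaving out 1 array leaves its culture in a single dye, so a dye effect no longer cancels in that culture.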

Results

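Transcript levels were measured in the extreme halophilic archaeon Halobacterium salinarum NRC-1, in a strain that lacks ura3, a gene of uridine synthesis used as a selection marker, and phr2, which encodes a photolyase that repairs ultraviolet damage with visible light. The strain was grown in rich medium to mid-log phase in 4 cultures of 50 mL in 125 mL flasks, with oxygen and light varied together. Shaking at 210 rpm gave the high-oxygen cultures and shaking at 100 rpm in a stoppered flask gave the low-oxygen cultures, and at each oxygen level 1 culture stood in light and 1 in a darkened flask. The RNA of each culture was hybridised on 2 two-colour arrays against a common reference RNA from mid-log NRC-1 cells, with the dyes exchanged between the arrays. The 2 arrays of a culture share its RNA and count as 1 replicate, so each oxygen or light level holds 2 cultures and each single condition holds 1. Every array carried 10752 spots in 2688 positions of 4 spots, of which 133 carry a gene symbol here and 2555 do not. On single arrays 1008 to 1745 positions stood above background in the culture channel, and 760 positions, 68 of them named genes, did so in both channels of all 8 arrays.

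The deleted genes were examined first. The ura3 gene carries the name pyrF on this array, and its position was not above background in the culture or the reference channel of any array. It has no fold for that reason and does not check the labels. Its measured log2 ratio to the reference was -0.28 ± 0.05 (SE, n = 4 cultures), below 0 on 8 of 8 arrays. No position is named phr2, bop, arcB, dmsA, gvpA, phr1, tbp or tfb in the annotation used, so these genes were not analysed here.

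The first comparison asks how transcript levels differed between low and high oxygen, with light taken into account. No gene changed past the threshold between low and high oxygen. Among named genes above background on at least 1 array of every culture and with the same sign in all 4 same-dye comparisons, the largest difference was that of gdhA1, a glutamate dehydrogenase linking carbon and nitrogen metabolism, with a log2 difference of 0.48 ± 0.15 (SE, n = 2 cultures per level), or 1.40-fold, adjusted p = 0.394. It was followed by secF, part of the protein export machinery, with 0.34 ± 0.11, and purL, an enzyme of purine synthesis, with 0.33 ± 0.11. On the other side stood uvrB, a subunit of the excision repair nuclease, with -0.28 ± 0.11, and the transducer htr6 with -0.22 ± 0.11. With plain background subtraction htr6 had -1.03 and uvrB -0.39. None of these passed, and the lowest adjusted p over all 2688 positions was 0.303. At an unadjusted p under 0.05 there were 265 positions, 121 with higher and 144 with lower values in low oxygen, against 134.4 by chance. Of the 133 named genes, 11 lay under that level against 6.65 by chance, 10 with higher values in low oxygen and 1, uvrB, with a lower value. Of the 10, tmk, hutG and pyrF, the name here of the deleted ura3, were above background on no array, serS on no low-oxygen array and purM on 1. No named gene passed when adjusted over the named genes alone, where the lowest adjusted p was 0.251.

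Other named genes had the same sign in all 4 same-dye comparisons without passing. With values above 0 stood the replication initiator gene orc7 (0.18), folP of folate synthesis (0.16), thiD of thiamine synthesis (0.16), purE of purine synthesis (0.16), glutamine synthetase glnA (0.14) and the tRNA synthetase genes ileS (0.14) and leuS (0.13). With values below 0 stood the tRNA synthetase gene hisS (-0.21), dpsA for an iron-binding ferritin-like protein (-0.19), gyrA for a DNA gyrase subunit (-0.18), the chemotaxis methyltransferase gene cheR (-0.17), arcC for the carbamate kinase of arginine fermentation (-0.16), sop1 for sensory rhodopsin I (-0.16), the transducer gene htr8 (-0.16), ndk (-0.10), arcA for arginine deiminase (-0.10) and the chaperone gene dnaK (-0.08). The value for sop2, sensory rhodopsin II, was 0.04 ± 0.11. The signs of ndk and arcA turned positive with median centring in place of loess. The value of dpsA shrank to -0.06 there and to -0.03 on the authors' deposited values. Those of thiD and glnA grew to 0.26 and 0.23 with median centring. The genes tmk, hutG and gatC were above background on no array, serS and bat on no low-oxygen array, and glpK and purM on neither array of the low-oxygen culture in light, so no fold is given for them.

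The gene groups fixed before the data were examined were tested with camera, and none passed for oxygen. All 7 measured genes of purine synthesis had values above 0, with a median log2 difference of 0.11 and adjusted p = 0.0729, and adjusted p = 0.938 with an estimated correlation. None of them passed by itself. Among members above background in every culture, purL (0.33 ± 0.11) and purE (0.16 ± 0.11) were the largest. Of the 11 named genes with an unadjusted p under 0.05 in the limma fit, 10 had higher values. Camera does not separate the purine group from such a shift of the named genes. Of the 13 measured genes of motility and phototaxis, 9 had values below 0, with a median of -0.05 and adjusted p = 0.734. The tricarboxylic acid cycle genes had a median of 0.06 over 6 genes, chaperones and proteasome 0.05 over 6, pyrimidine synthesis 0.03 over 5, DNA repair 0.02 over 4 and cobalamin synthesis 0.01 over 4, with adjusted p of 0.734 or higher. The arginine fermentation group (arcA and arcC), purple membrane (hop and bat), anaerobic respiration on dimethyl sulfoxide (moaA and moaC), respiratory chain (nuoL and sdhC), oxidative stress (msrA and dpsA), ribosomal proteins (rpl12p, as the symbol pattern fixed for this group did not match rpmC) and phosphate uptake (phoU) had under 4 measured genes and were not tested, and 9 further groups had none.

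The count of 0 for oxygen was sensitive to the treatment of dim spots and of the spread. With a prior that follows intensity, whose degrees of freedom were infinite for part of the positions, 48 passed, among them gdhA1 (adjusted p = 7.8e-06), purL (adjusted p = 0.0202) and secF (adjusted p = 0.0202). On the authors' deposited log ratios 196 passed, 24 higher and 172 lower in low oxygen, with gdhA1, purL and thiD among the higher. Restricting the fit to the 760 positions above background on every array, a choice made after seeing the data, gave 32, with purL (adjusted p = 0.003) and phoU (adjusted p = 0.026) as the named genes.

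The oxygen effects of the light pair and of the dark pair of cultures were set against each other across positions, without a test, as each is 1 culture against 1. Pearson's r was 0.128 over all 2688 positions and 0.412 over the 760 positions above background on every array, where positions are not independent replicates. For gdhA1 the log2 difference between low and high oxygen was 0.17 in light and 0.79 in dark, so its mean came mostly from the dark pair. For purL the log2 difference between low and high oxygen was 0.23 in light and 0.42 in dark, and for dpsA it was -0.18 and -0.21. For phoU, a regulator of phosphate uptake, it was 0.02 in light and 0.51 in dark. Leaving out the first array of the low-oxygen culture in light lowered r over all positions to 0.00977. In r over all positions, omitting other single arrays gave 0.0797 for the second of high oxygen in light, 0.0186 and 0.202 for the first and second of high oxygen in dark, and 0.0231 for the second of low oxygen in dark.

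**Figure D1:**
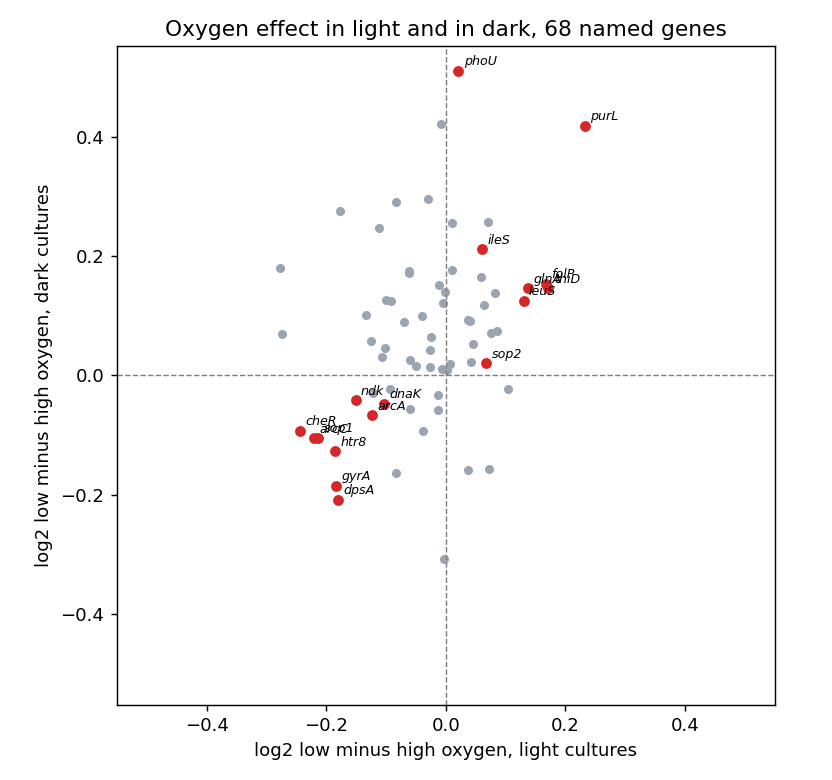
Each point is 1 of the 68 named genes above background in both channels of all 8 arrays; the x axis gives the log2 difference between low and high oxygen in the light cultures and the y axis that in the dark cultures, with genes named in the text in red. Of these genes, 39 lie in the quadrants of equal sign, with purL at 0.23 and 0.42 and dpsA at -0.18 and -0.21, and the correlation across the plotted genes was 0.322.

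The second comparison asks how transcript levels differed between light and dark, with oxygen taken into account. No gene changed past the threshold between light and dark. The named genes given here had the same sign in all 4 same-dye comparisons and were above background on at least 1 array of every culture. Above 0 stood purF of purine synthesis with a log2 difference of 0.17 ± 0.11 (SE, n = 2 cultures per level), sdhC for a succinate dehydrogenase subunit with 0.15 ± 0.11, the chemotaxis response regulator gene cheY with 0.11 ± 0.11, glmS with 0.11 ± 0.11, thrS with 0.09 ± 0.11, ndk with 0.07 ± 0.11 and gyrA with 0.06 ± 0.11. Below 0 stood purL with -0.18 ± 0.11, orc7 with -0.13 ± 0.11, gatA with -0.12 ± 0.11, the enolase gene eno with -0.12 ± 0.11, leuS with -0.12 ± 0.11, lpdA with -0.11 ± 0.11, uvrB with -0.11 ± 0.11 and alaS with -0.10 ± 0.11. The genes gatC, hutI and mch were above background in the culture channel of no array, aroC in no dark culture and serS in no low-oxygen culture, so no fold is given for them.

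Genes of light sensing showed no call either. The log2 difference between light and dark was -0.01 ± 0.11 for sop1 and -0.04 ± 0.11 for sop2. In arginine fermentation it was 0.06 ± 0.11 for arcA and -0.003 ± 0.11 for arcC. The transducer gene htr18 did not pass (adjusted p = 0.762) and has no fold, as it was above background on neither array of the low-oxygen culture in dark. That group had 8 of 13 genes above 0, a median of 0.01 and adjusted p = 0.705. The median was 0.06 for purine synthesis, 0.05 for pyrimidine synthesis, 0.05 for chaperones and proteasome, 0.03 for cobalamin synthesis, 0.01 for the tricarboxylic acid cycle, whose mean was -0.03, and -0.12 for DNA repair, and no group passed, with 0.628 the lowest adjusted p by camera. Over all positions the limma fit called 0, with 157 at an unadjusted p under 0.05 against 134.4 by chance and a lowest adjusted p of 0.40. Of the named genes 5 lay under the unadjusted level against 6.65 by chance, and none passed over the named genes alone. Across positions the light effect in high oxygen and that in low oxygen had r = -0.0231, and 0.114 over the 760 positions above background.

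The third comparison sets the mean of the 4 cultures against the reference RNA, which came from NRC-1 cells and is 1 RNA, so its own spread is left out and strain, deletions and growth are not told apart. The phosphate regulator gene phoU was 1.85-fold lower, with log2 -0.89 ± 0.07 (SE, n = 4 cultures) and adjusted p = 0.000117. The ribosomal protein genes rpl12p (-0.61 ± 0.06) and rpmC (-0.32 ± 0.06) were 1.52-fold and 1.25-fold lower. Also lower on all 8 arrays were sucC for succinyl-CoA synthetase (-0.54 ± 0.07), purL (-0.52 ± 0.06), hemA of haem and cobalamin precursor synthesis (-0.39 ± 0.06), the malate dehydrogenase gene mdh (-0.31 ± 0.06), the lysyl-tRNA synthetase gene lysS (-0.31 ± 0.06), the glutamate dehydrogenase gene gdhA2 (-0.31 ± 0.06), citrate synthase citZ (-0.22 ± 0.06) and gyrA (-0.26 ± 0.05). For gdhA1 the value was -0.39 ± 0.08, below 0 on 7 of 8 arrays, and it ranged from -0.81 in the high-oxygen dark culture to -0.02 in the low-oxygen dark culture. Of the 8 fits that each left out 1 array, phoU kept its call in 7, rpl12p and purL in 6, sucC in 5, hemA, rpmC, mdh, gyrA and gdhA1 in 4, gdhA2 in 3, lysS in 2 and citZ in 1, and none kept it with plain background subtraction. The values of these genes stayed below 0 in all these fits, with phoU between -0.96 and -0.82 without 1 array.

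Fewer named genes were higher in the cultures, 6 against 27 lower. On all 8 arrays dpsA (0.24 ± 0.05, 1.18-fold), the argininosuccinate lyase gene argH (0.21 ± 0.06), pan1 for a proteasome-activating ATPase (0.20 ± 0.05), cheY (0.20 ± 0.06) and arcC (0.20 ± 0.06) were higher, with adjusted p from 0.0144 for dpsA to 0.0347 for arcC. The chemotaxis kinase gene cheA was above 0 on all 8 arrays with 0.11 ± 0.05 and adjusted p = 0.19, which did not pass. The transducer gene htr18 passed as higher with adjusted p = 0.003 and has no fold, as it was above background on neither array of the low-oxygen culture in dark. Of 8 fits that each left out 1 array, the call was lost in 6 for dpsA, 7 for cheY, 3 for htr18 and 8 each for argH, pan1 and arcC, and all were lost with plain background subtraction. Their values moved less: without 1 array dpsA lay between 0.20 and 0.28, cheY between 0.14 and 0.26, argH between 0.17 and 0.24, pan1 between 0.17 and 0.23 and arcC between 0.19 and 0.20, and with plain subtraction dpsA had 0.24, while the prior degrees of freedom were 1.60 there and 7.38 in the fit reported. Other settings moved some of them more. The value of dpsA was 0.16 with median centring and 0.10 on the authors' deposited values. On the high-gain scan, where saturated spots stay clipped, dpsA was -0.001, argH 0.13, cheY 0.13 and arcC 0.09, while pan1 was 0.20. Not passing were arcA (0.11 ± 0.05), sop1 (0.09 ± 0.06) and sop2 (0.01 ± 0.05).

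Among the gene groups, the tricarboxylic acid cycle stood lowest against the reference. All 6 measured genes had values below 0, with a median of -0.23, and 4 passed (sucC, mdh, sucD and citZ), also when adjusted over the list alone; sucD had -0.24 ± 0.06. The group passed by camera with adjusted p = 0.0267, and had adjusted p = 0.506 with an estimated correlation. Camera set it against all other positions, most of them without a symbol. Named genes were called lower in 27 cases and higher in 6, positions without a symbol in 259 and 360. The call thus does not separate this group from the lower values of named genes in general. In purine synthesis 3 of 7 genes were lower (purL, purF with -0.19 ± 0.05 and purD with -0.19 ± 0.06), and the group had adjusted p = 0.124. In pyrimidine synthesis carB was lower (-0.25 ± 0.05) beside pyrF, which was not above background, and the group had adjusted p = 0.236. Of 4 cobalamin genes cbiT was lower (-0.20 ± 0.05), with adjusted p = 0.162 for the group. In motility and phototaxis 11 of 13 genes had values above 0, 2 of which passed (htr18 and cheY), with a median of 0.05 and adjusted p = 0.162 for the group. In the group of chaperones and proteasome pan1 was higher and panB, whose symbol is in use for more than 1 function and was matched by name only, was lower (-0.27 ± 0.06), with adjusted p = 0.267 for the group. None of the 4 DNA repair genes passed, and that group had adjusted p = 0.745. The lower values of purF, purD, cbiT and panB came mostly from arrays with the culture in Alexa 647. In Alexa 532 they ranged from -0.18 to 0.17, -0.10 to 0.03, -0.08 to 0.01 and -0.13 to -0.01. In Alexa 647 they ranged from -0.49 to -0.15, -0.44 to -0.29, -0.49 to -0.32 and -0.625 to -0.22. For purL all values lay below 0 in both dyes, from -0.57 to -0.12 and from -0.88 to -0.33. Some other lower genes also had their larger decreases in Alexa 647. In Alexa 532 and Alexa 647, rpl12p had -0.44 to -0.27 and -1.05 to -0.68, and hemA -0.25 to -0.09 and -0.75 to -0.48. For mdh these ranges were -0.20 to -0.06 and -0.63 to -0.37, and for sucD -0.21 to 0.14 and -0.58 to -0.25. The same held for rpmC and hisI. For phoU, sucC, citZ, lysS, gyrA, gdhA1 and gdhA2 the ranges of the 2 dyes overlapped. Of the 8 fits that each left out 1 array, carB and panB kept their call in 3, sucD in 1 and purF, purD and cbiT in 0.

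**Figure D2:**
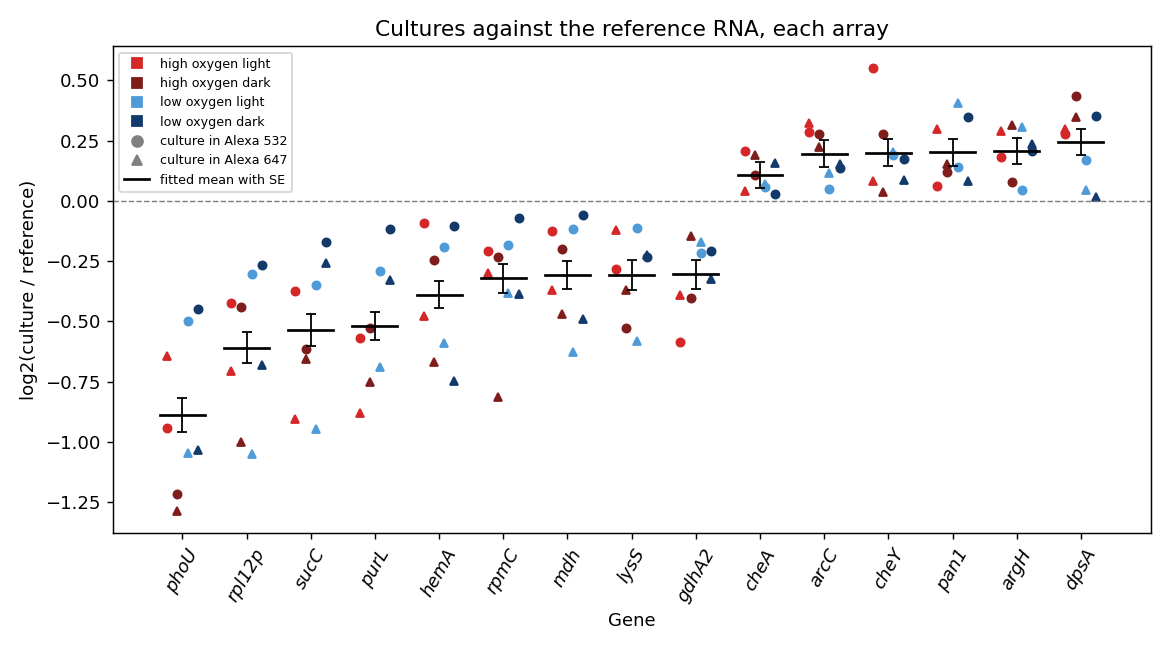
Each marker is the log2 ratio of culture to reference of a gene on 1 array, coloured by culture and shaped by the dye of the culture, with the fitted mean of the 4 cultures and its SE as a bar; the x axis lists the named genes with the largest values of the same sign on all 8 arrays. The values of phoU lie around a mean of -0.89 and those of dpsA around 0.24, and cheA did not pass the test.

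Over all positions, the limma fit called 652 against the reference, 366 higher and 286 lower, with 1015 at an unadjusted p under 0.05, and 333 of the calls had the same sign on all 8 arrays. Among named genes 33 passed, 6 higher and 27 lower, and 33 did so when adjusted over the named genes alone. Among positions with no symbol here and the same sign on all 8 arrays, position_2217 was lower, above background in the reference on 8 of 8 arrays and in the culture channel on 1 of 8, so no fold is given. The highest was position_0399, with 1.32 ± 0.06, above background in the culture channel on 8 of 8 arrays and in the reference on 5 of 8. Of the calls, 107 were at positions above background on no array, which have no fold. The count was 0 with plain background subtraction and 97 from the arrays with the culture in Alexa 647 alone. Omitting single arrays gave 303 and 196 for the first and second of high oxygen in light, 52 and 402 for high oxygen in dark, 32 and 551 for low oxygen in light, and 341 and 113 for low oxygen in dark.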

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

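Except for the test of both dye orientations in the comparison with the reference, the tests in this part were chosen after the results were seen. Of the genes named for oxygen or light, 1 moved one way in one setting and the opposite way in the other on both dyes. For arcC, the carbamate kinase gene of arginine fermentation, the log2 difference between light and dark was 0.05 in high oxygen and -0.06 in low oxygen, a difference of 0.116 that was not tested. Among all 133 named genes, 21 did so for light and 16 for oxygen, where 16.6 would by chance.

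The arrays with the culture in the same dye were more alike than the 2 arrays of one culture. Gene-specific dye bias stays open: the difference between the dye orientations of a position correlated between different cultures with r of at least 0.353, but the pattern itself brings such a correlation about, so this test does not decide. Noise near background does not account for all of it, because over the 760 positions above background the highest r of the 2 arrays of a culture was 0.603, below the median of 0.773 for arrays of one orientation. Exchanged culture labels alone do not account for the pattern over all positions. Arrays in different dyes reached r of 0.26 within a culture and 0.266 between cultures at most, while same-dye pairs started at 0.426. These values argue against that explanation, whichever arrays are partners. Whether an array carries the label of another culture stays open: only 4 of 8 arrays had their own partner as the closest array of the other dye over the 760 positions. The partners, with a median r of 0.526 over these positions, were no closer than arrays of different cultures in the other orientation, with 0.525. Cultures that differ little from one another would bring this about, but so would noise of the arrays or a wrong label. This biological explanation stays open too.

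Named genes were mostly lower in the cultures than in the reference, 27 against 6, while positions without a symbol were more often higher, 360 against 259. The number of named calls, 33, depended on single arrays: it was 0 without the first array of the low-oxygen culture in light, 1 without the first of high oxygen in dark, 26 without the second of low oxygen in light, and 0 with plain background subtraction. Each fit without 1 array also leaves 1 culture in a single dye, so the array and the lost dye balance cannot be told apart there. Spot intensity does not account for the many lower named genes, as 0.74% of 10000 draws of unnamed positions matched on intensity held as many lower calls or more. Remaining dye bias stays open. In both dye orientations 26 of the 27 lay below 0, but this counts signs and not sizes. For cbiT the values were -0.08 to 0.01 with the culture in Alexa 532 and -0.49 to -0.32 in Alexa 647. For phoU they were alike, -1.21 to -0.45 and -1.29 to -0.64. A difference between the strain's cultures and the reference cells in growth or genotype may underlie the pattern and was not tested.

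On the authors' deposited values 172 of 196 oxygen calls were lower in low oxygen. An intensity trend left in those values is a candidate explanation: the median log2 difference of the dimmest 25% of positions lay -0.213 from that of the brightest, against -0.0477 after normexp and loess, and 89 of the lower calls lay in the dimmest 25%. A biological explanation by oxygen was not tested apart from it.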

How the results depend on the processing

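Tests on the estimated correlation under other settings, the low-gain scan, the high-gain scan and the positions above background were chosen after the results were seen. The oxygen count of 0 became 9 with no background correction, 9 without the dimmest 25%, 48 with a prior following intensity (25 higher; prior degrees of freedom from 4.74 to infinite), 196 on the authors' values (24 higher), 21 on the low-gain scan and 32 at positions above background on all arrays (13 higher), where they were infinite; it was 0 in every fit without 1 array. The diagonal split of the cultures, which is another contrast, had 106 positions at an unadjusted p under 0.05 with light in the model, against 265 for oxygen in the model with light, and 150 with oxygen in the model. The light count of 0 became 1 with a prior following intensity and 2 on the low-gain scan. In the fit with the culture as random block the estimated correlation of the 2 arrays of a culture was -0.305. That makes 2 arrays of one RNA count for more than 2 independent ones and narrows the error. The 652 calls against the reference became 0 with plain background subtraction, 97 with the culture in Alexa 647 alone, 362 on the high-gain scan, all of them among the 652, 979 with all 8 arrays and the culture as random block, and 32 to 551 without 1 array. The share of higher calls among them, 56.1%, was 47.8% with median centring (385 higher, 421 lower), 84.4% without the first array of low oxygen in light (27 higher, 5 lower), 76.0% without the second of high oxygen in light, 73.1% without the first of high oxygen in dark and 69.9% without the second of low oxygen in dark.

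The correlation of oxygen effects (0.128) was 0.263 with no background correction, 0.0628 with plain subtraction, 0.219 with median centring, 0.453 on the authors' values, 0.218 without the dimmest 25%, 0.186 in Alexa 532 and 0.0438 in 647 alone, 0.215 on the low-gain scan, 0.412 above background and 0.00977 to 0.202 without 1 array. That of light effects (-0.0231) was 0.0406, 0.0264, 0.0157 and 0.112 in the first 4 of these, 0.134 in Alexa 532 alone, 0.141 on the low-gain scan, 0.114 above background and -0.125 to 0.116 without 1 array. No oxygen list passed, but 1, purine synthesis, did with no background correction (adjusted p = 0.0197), median centring, scaling and the median of the spots, and 1 with the culture as random block; 2 did on the authors' values, with the tricarboxylic acid cycle, and 0 to 1 without 1 array. All these used the preset correlation. With an estimated one, tried afterwards, none of these lists passed where camera was run on the cultures (lowest adjusted p = 0.537). That estimate is poorly determined with 1 residual degree of freedom, so this does not count against the lists. No light list passed under any setting.

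Of 569 values of 24 genes for oxygen 18 reversed, of 474 for light 25 and of 691 against the reference 9, where 219 lost their call. For oxygen, on the low-gain scan orc7 was -0.015 and sop2 -0.021; on the high-gain scan, where saturated spots stay clipped so that a turned sign is no evidence of a change, thiD was -0.0083, glnA -0.0091, dpsA 0.0044 and dnaK 0.033 (59, 54, 62 and 28 of 64 spots saturated); with median centring ndk was 0.015 and arcA 0.026, and on the authors' values 0.034 and 0.043; phoU was -0.073 in Alexa 647 alone. For light, on the low-gain scan glmS was -0.014, gyrA -0.048, uvrB 0.080 and arcC 0.012; in Alexa 647 alone sop1 was 0.10, sop2 0.0075, arcA -0.063 and arcC 0.032; arcC was 0.018 with no background correction and 0.033 on the authors' values. Against the reference dpsA was -0.0011 and sop2 -0.0091 on the high-gain scan, sop2 -0.013 on the authors' values, and in Alexa 532 alone sop1 was -0.088 and sop2 -0.17. Without 1 array, dnaK ranged from -0.19 to 0.036 and sop2 from -0.060 to 0.15 for oxygen; cheY from -0.0045 to 0.23, thrS from -0.013 to 0.19, sop1 from -0.15 to 0.13, sop2 from -0.15 to 0.063, arcA from -0.0082 to 0.13 and arcC from -0.020 to 0.014 for light; and sop2 from -0.041 to 0.064 against the reference. Values that kept their sign but moved by over 1.5 times were, for oxygen, orc7 (0.098 to 0.26), folP (0.014 to 0.31), glnA (0.082 to 0.20), ileS (0.071 to 0.20), leuS (0.063 to 0.19), phoU (0.12 to 0.41), dpsA (-0.28 to -0.11), cheR (-0.23 to -0.11), sop1 (-0.30 to -0.020) and arcA (-0.17 to -0.025), for light, purF (0.015 to 0.32), glmS (0.051 to 0.16), ndk (0.044 to 0.094), gyrA (0.011 to 0.10), purL (-0.27 to -0.077), orc7 (-0.21 to -0.047), leuS (-0.19 to -0.056), lpdA (-0.15 to -0.067) and uvrB (-0.17 to -0.039), and against the reference purF (-0.27 to -0.12) and sop1 (0.022 to 0.16). These ranges cover only the fits without 1 array. Other settings moved some oxygen values further with the same sign. With plain subtraction htr6 was -1.03, orc7 0.78 and phoU 0.48, and thiD was 0.26 with median centring and 0.28 on the authors' values. Apart from saturation and the trend in the authors' values, no cause was tested.

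No paired analysis was possible because the labels give no replicate numbers that pair cultures beyond the oxygen and light levels, which the additive fit already uses. Quality flags could not be ignored as planned, since the scans hold no flag column, pyrF gave no value above background to recompute, and phr2 has no named position. Signal over background limits the dim positions: 719 positions were above background on no array.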

Other observations

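Genes of other groups were examined in lists added once the gene names had been seen, so they are not independent of that choice. Against the reference, 2 of 6 histidine synthesis genes were lower, hisI (-0.22 ± 0.05, below 0 on 8 of 8 arrays, its call kept in 1 of 8 fits without 1 array) and hisF, which has no fold because it was above background on neither array of the low-oxygen culture in light, with adjusted p = 0.156 for the group by camera. Of 12 aminoacyl-tRNA synthetase genes 10 had values below 0 and 2 passed, with adjusted p = 0.118. In glutamate and glutamine metabolism gdhA1 and gdhA2 were lower and 3 genes did not pass (adjusted p = 0.156). All 4 chemotaxis proteins had values above 0 and 1, cheY, passed (adjusted p = 0.156). Of 7 transducer genes 1, htr18, passed (adjusted p = 0.385), and all 4 glycolysis and gluconeogenesis genes had values below 0 with none passing (adjusted p = 0.156).

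For oxygen, all 5 genes of glutamate and glutamine metabolism had values above 0, with a median of 0.15 and gdhA1 highest at 0.48. The group did not pass by camera, with adjusted p = 0.0557, and had adjusted p = 0.798 with an estimated correlation. All 4 genes of glycolysis and gluconeogenesis had values above 0 with a median of 0.10 (adjusted p = 0.494). For the transducers 5 of 7 values lay below 0 (adjusted p = 0.698), as they did for 3 of 4 chemotaxis proteins (adjusted p = 0.698). The tRNA synthetases (median 0.02) and histidine synthesis (median 0.004) had values on both sides. For light 6 of 7 transducers had values above 0, with a median of 0.07 and adjusted p = 0.32, and none of the other added groups had an adjusted p under 0.961. Lists of histidine degradation and thiamine synthesis had under 4 genes and were not tested.

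Among positions without a symbol, position_0257 had the highest log2 difference between low and high oxygen of those with equal sign in all 4 same-dye comparisons, 0.69 ± 0.13, with adjusted p = 0.303. Its gene is not named here.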
